A study of Arabidopsis thaliana with 18 samples.

How the data were processed

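Wild-type Arabidopsis thaliana seedlings were grown for 19 days at 22 °C in continuous white light and then given 1 of 3 light treatments, per the labels: 2 h of further white light (WL), 2 h of darkness (D), or a pulse of far-red light followed by 2 h of darkness (FRD). RNA was taken separately from the blades and the petioles of rosette leaves 3 and 4 and labelled with biotin for Affymetrix Arabidopsis arrays. The 18 arrays fall into 6 groups of 3, and the series description calls the 3 replicates of a group independent biological replicates. The number of arrays limits the precision of each value.

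The values as deposited are linear ratios. In each tissue the median of the 3 white-light arrays was exactly 1 in all 22810 probe sets, while in each of the 4 other groups this held for 20 to 46 probe sets. The authors therefore divided each probe set by the white-light median of its own tissue before the ratios were deposited, a reading that rests on the values since neither the labels nor the file headers state it. How the arrays were summarized, background-corrected and scaled before that division is not given in the sources used here. A division of this kind drops out of every difference between light treatments within a tissue, and out of the difference of 2 such differences between tissues. It removes the level of each gene: signal over background is unknown, bright and dim probe sets cannot be told apart, and petioles could not be compared with blades in white light. Array medians lay between 0.936 and 1.02. There were 3 missing values, 1 in a petiole D array and 2 in a petiole FRD array, both with replicate number 3.

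The 64 control probe sets were left out, and 22746 probe sets were tested. The platform's probe annotation gave 1 gene for 13513 of the 22810 probe sets and several genes for 503, which were not named. The other 8794, controls included, are not in that table and are unnamed here. Entrez numbers matched the RefSeq gene table (assembly TAIR10.1) for 13436 probe sets. Only 1580 of them, for 1552 genes, carry a symbol other than a locus code, so many well-known light and hormone genes have no named probe set here. Coordinates are not given because the array files name no genome build.

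Log2 ratios were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 18 arrays (12 residual degrees of freedom) and empirical Bayes moderation (prior degrees of freedom 1.459). Benjamini-Hochberg adjustment was applied within each comparison over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Calls with an absolute log2 fold change of at least 1 were also counted. The 6 light comparisons were FRD against D, D against WL and FRD against WL in each tissue. The 3 differences between tissues are the petiole change minus the blade change. Log2 values are rounded to 2 decimals, with a final 0 dropped. Errors beside fold changes are standard errors of this fit, which pools the spread over the 6 groups, and those beside group means are SDs over 3 arrays. All limma tests are two-sided.

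The design fixed before the data were examined assumed expression levels. It named a pseudocount at the 10th percentile of all values and a variance trend on the mean level. Because the values are ratios, the fit used log2 ratios with no pseudocount and no trend, a choice made after the unit was known and before any test. The planned scale and the planned trend were run as alternatives. A planned filter on dim probe sets, the comparison of petiole with blade in white light and 2 marker checks of the tissue labels were not made, because ratios carry no level.

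Of 24 gene lists fixed before the data were examined, 7 had at least 3 members with a named probe set and were tested. A further 18 lists were assembled from the symbols in the probe annotation after it had been read and before any test, and are called added lists. Where a gene had several probe sets, that with the smallest residual SD was used in place of the planned brightest one. Lists were tested with camera on the limma fit at a preset inter-gene correlation of 0.01, adjusted over the planned lists and over the added lists separately within a comparison. The tests were repeated with an estimated correlation, with fry, which asks only whether the genes of a list move on balance one way, and with the replicate number as a block.

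Named genes follow a rule fixed before the data were examined: per comparison, up to 8 genes with the largest rise and 8 with the largest fall among called probe sets with a symbol whose compared arrays did not overlap (5 and 5 for differences between tissues), up to 4 members per list and any needed to describe a count, and 9 light-response genes of which IAA29 alone has a named probe set. Chance gives non-overlapping groups to 10% of probe sets at 3 against 3. A requirement on level in that rule was dropped. Up to 3 rises and 3 falls known by locus code alone were added after the number of calls with a symbol had been seen.

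The fit was tested on simulated ratios centred as in the deposited ones, with 200 of 22746 probe sets changed and the observed residual SDs. For FRD against D in petioles it recovered 2.99% of changes of 0.5, 26.9% of changes of 1 and 63.6% of changes of 2 log2 units, with 1 false call. For D against WL in blades these shares were 8.96%, 38.8% and 63.6%, with 3 false calls. For the FRD against D difference between tissues they were 0%, 17.9% and 56.1%, with 6 false calls among 55. In 100 simulated runs for FRD against D in petioles, a list of 12 genes shifted by 1 was called 100 times and an unshifted one 6 times at an unadjusted p under 0.05. Simulated errors were independent between genes, so these runs do not test what correlation between genes does to list calls. The 200 changed probe sets are also far fewer than the 2542 called for darkness in blades, so the shares recovered need not hold there.

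Alternatives were a pseudocount at the 10th or 25th percentile of all ratios (0.553 and 0.814), floors at the 1st and 10th percentile (0.131 and 0.553), alignment of the 75th percentile of each array, quantile normalization, array quality weights, the replicate number as a block, a fit of the compared arrays alone, the variance trend, the leaving out of each array in turn, and the leaving out of all arrays with replicate number 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.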

Results

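Transcript abundance was measured in leaf blades and petioles of 19-day-old Arabidopsis seedlings kept for 2 h in white light (WL), moved to darkness for 2 h (D), or given a far-red pulse and then 2 h of darkness (FRD). Far-red light converts phytochromes to their inactive form, and a far-red pulse before darkness is a common way to set off shade avoidance, in which petioles elongate. FRD against D therefore asks for the response to the pulse, D against WL for the response to darkness, and FRD against WL for both together. Each of the 6 groups holds 3 arrays. A value is the ratio of a probe set to its white-light median in the same tissue, so the changes below are relative and the level of a gene is unknown.

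The far-red pulse changed 148 probe sets in blades and 249 in petioles among the 22746 tested. Darkness changed 2542 in blades and 1274 in petioles, and the pulse with darkness changed 2537 and 1891 against white light. Changes of at least 2-fold made up 119 and 187 of the calls for the pulse, 968 and 577 of those for darkness, and 1002 and 919 of those for both together, blades first.

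**Figure D1:**
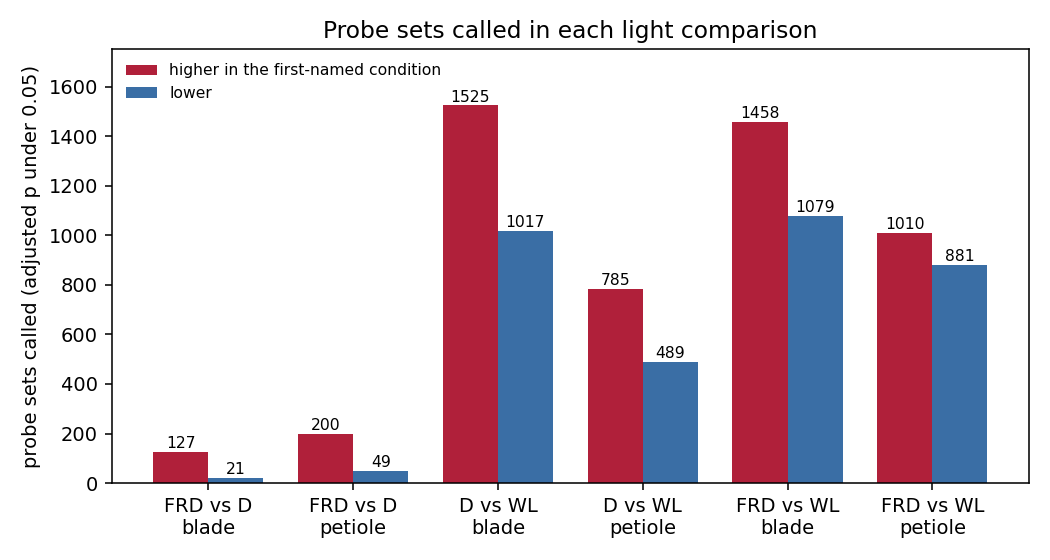
Bars give the number of probe sets called at an adjusted p under 0.05 (vertical axis) that were higher (red) or lower (blue) in the first-named of 2 light treatments, for each tissue (horizontal axis, 3 arrays per group). The pulse raised 127 and lowered 21 probe sets in blades and raised 200 and lowered 49 in petioles.

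In blades, the genes with a symbol that the far-red pulse raised most were early auxin genes. Only 10 of the 148 called probe sets carry a symbol, and unnamed ones rose more, by up to 7.17 log2 units. GH3.3 (AT2G23170), an enzyme that joins auxin to amino acids, rose by 5.33 ± 0.82 log2 units over darkness, a 40.2-fold change (limma adjusted p = 0.0057, 3 arrays per group). The Aux/IAA repressor genes IAA29 (AT4G32280) and IAA30 (AT3G62100) rose by 4.3 ± 0.38 and 2.91 ± 0.38, and WES1 (AT4G27260), a second GH3 enzyme, by 2.6 ± 0.23. HAT2, a homeodomain-leucine zipper gene known to respond to shade, rose by 2.58 ± 0.29. The expansin gene EXPA8 rose by 2.34 ± 0.36, BIM1, a basic helix-loop-helix factor of brassinosteroid signalling, by 1.57 ± 0.13, and YUC2, a flavin monooxygenase of auxin synthesis, by 1.52 ± 0.26. Adjusted p lay between 3.06e-05 and 0.0125 for these 8 genes.

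Only 2 genes with a symbol met the rule for a fall in blades. NAI1, a transcription factor needed to form endoplasmic reticulum bodies, fell by 3.18 ± 0.5 (adjusted p = 0.00694), and SFP1, a member of a sugar transporter family, fell by 1.27 ± 0.23 (adjusted p = 0.0169). Among genes known by locus code, AT5G02540 rose by 3.6 ± 0.28, AT5G55800 by 3.23 ± 0.66 and AT5G66590 by 2.62 ± 0.23. The falls were those of AT5G09430 (-3.83 ± 0.76), AT1G24640 (-2.71 ± 0.43) and AT5G62360 (-2.15 ± 0.41).

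The GH3 list rose after the pulse in blades: 2 of its 5 measured members were called over all genes, GH3.3 and WES1, and 3 adjusted over the list alone, where GH3.17 joined them at 2.34 ± 0.49 (camera adjusted p = 3.26e-10, and 0.00015 with an estimated correlation). Of 7 Aux/IAA members, IAA29 and IAA30 were called, over all genes and adjusted over the list alone. The test placed that list as raised (adjusted p = 0.0427) and its mean was 0.80, but its median was -0.21 and the call was lost with an estimated correlation (adjusted p = 0.084). Among 3 genes of auxin synthesis YUC2 was called over all genes, while YUC4 stood at 1.79 ± 1.2, and the list itself was not called (adjusted p = 0.12). Adjusted over that list alone, YUC6 was also called, lower at -2.17 ± 0.84. Of 14 expansin and xyloglucan endotransglucosylase genes in blades, EXPA8 alone was called, both over all genes and adjusted over the list alone (list adjusted p = 0.12).

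Of the 16 genes named for this comparison, 11 stayed called when any 1 array of the compared groups was left out, and AT5G09430, AT5G55800, AT5G62360, SFP1 and YUC2 did not. The count of 148 fell to 32 with quantile normalization (7 of the 16 named genes), to 10 (none of the 16 named genes) in a fit of the 6 compared arrays alone, and to 92 without blade FRD replicate 2. EXPA8, FRD vs D, blade, dropped to 1.28 (adjusted p = 0.193) with ratios floored at their 1st percentile, and a floor at the 10th percentile ended its call and those of AT5G55800, AT5G09430 and AT1G24640. GH3.3 was not called with a variance trend on the mean log2 ratio (adjusted p = 0.754).

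In petioles, the pulse raised early auxin genes too. Here 18 of the 249 called probe sets carry a symbol, and unnamed ones rose by up to 5.75. GH3.3 rose by 4.99 ± 0.82 (adjusted p = 0.00745), IAA29 by 4.22 ± 0.38, IAA30 by 4.12 ± 0.38 and WES1 by 3.95 ± 0.23, which is 15.5-fold (adjusted p = 3.02e-06). HAT2 rose by 2.2 ± 0.29. MGL (AT1G64660), which encodes methionine gamma-lyase, rose by 2.6 ± 0.23 (adjusted p = 6.49e-05). The transcription factor gene BZIP61 rose by 1.97 ± 0.41, and FHL, whose protein carries phytochrome A into the nucleus, by 1.68 ± 0.36. The cytochrome P450 gene CYP71B22 fell by 1.53 ± 0.22 (adjusted p = 0.00276), and MYC4, a transcription factor of jasmonate signalling, fell by 1.02 ± 0.22 (adjusted p = 0.0432).

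Genes known by locus code changed in petioles as well. AT5G02580 rose by 5.81 ± 1.02, AT5G62280 by 4.57 ± 0.79 and AT5G57670 by 3.68 ± 0.73. Lower after the pulse were AT1G52770 (-3.47 ± 0.77), AT4G08340 (-3.35 ± 0.74) and AT3G28750 (-2.82 ± 0.51), and adjusted p ran from 0.0111 to 0.0495 for these 6 genes.

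**Figure D2:**
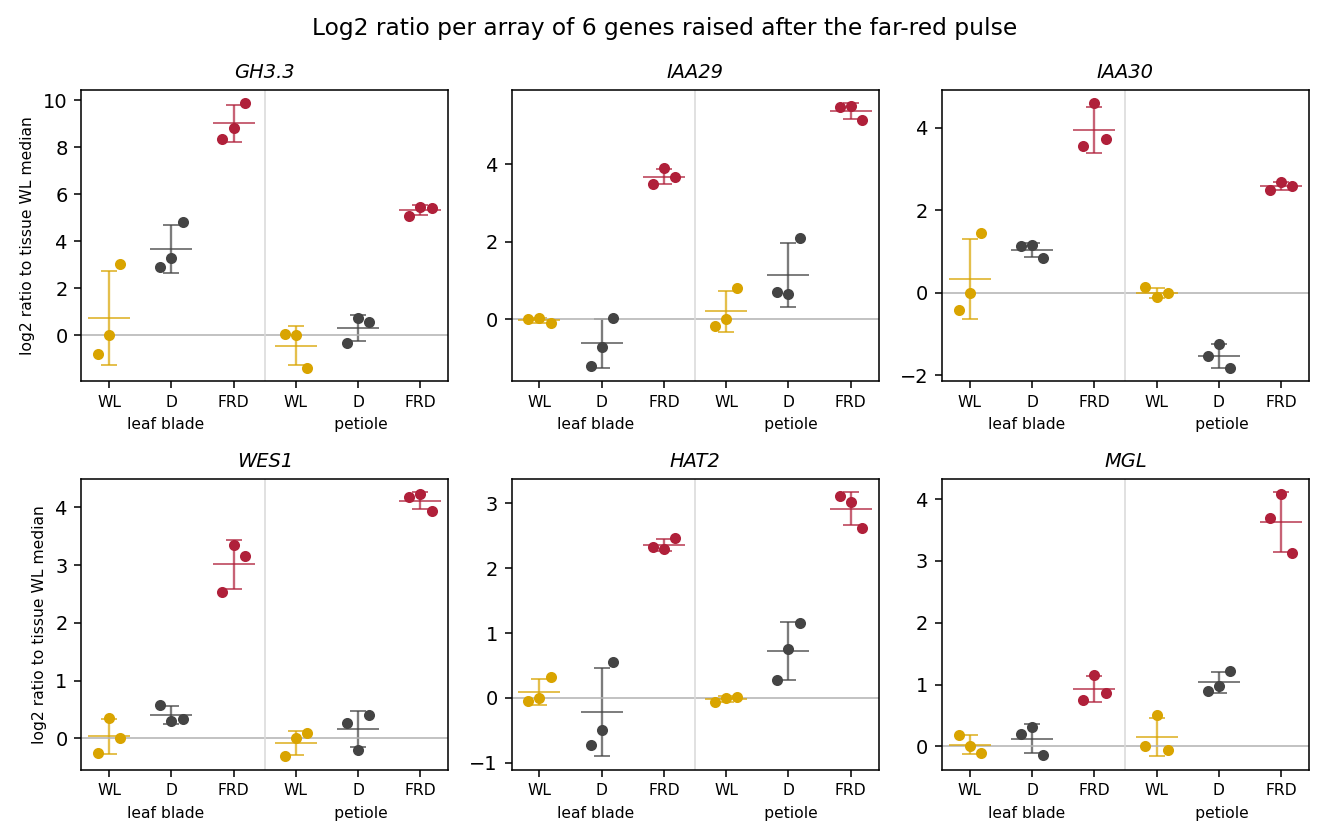
Each panel shows 1 gene, with the log2 ratio to the white-light median of its tissue on the vertical axis and the 6 groups on the horizontal axis, blades to the left and petioles to the right. Points are single arrays, and bars show the mean and SD of 3 arrays. IAA29 averaged 3.68 in blade FRD arrays and 5.37 in petiole FRD arrays, against -0.62 and 1.14 in the D arrays.

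In petioles the Aux/IAA, GH3 and cell wall lists all rose after the pulse. Of 7 Aux/IAA genes, 2 were called over all genes and 3 adjusted over the list alone, where IAA20 joined at 2.73 ± 0.78 (list median 1.17, camera adjusted p = 2.44e-07, 0.000476 with an estimated correlation). All 5 GH3 genes were called adjusted over the list alone, 2 of them over all genes. The 4 that rose were GH3.3, GH3.1 at 4.27 ± 1.18, WES1 and GH3.17 at 1.32 ± 0.49, while GH3.9 fell by 0.65 ± 0.3 (list adjusted p = 2.44e-07, 0.000476 with an estimated correlation). The 14 expansin and xyloglucan endotransglucosylase genes, whose products loosen or remodel the growing wall, had a median of 0.89 and 12 positive values (adjusted p = 3.01e-06, 0.0183 with an estimated correlation). EXPA8, at 1.66 ± 0.36, was the single member called over all genes. Adjusted over the list alone 5 were called: EXPA8, XTH33 at 2.35 ± 0.69, XTH19 at 2.21 ± 0.66, EXLA2 at 1.76 ± 0.45 and EXPB1 at 1.38 ± 0.33. An added list of all 28 such genes with a symbol had a smaller median of 0.24, and its call was lost with an estimated correlation (adjusted p = 0.026 against 0.27).

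**Figure D3:**
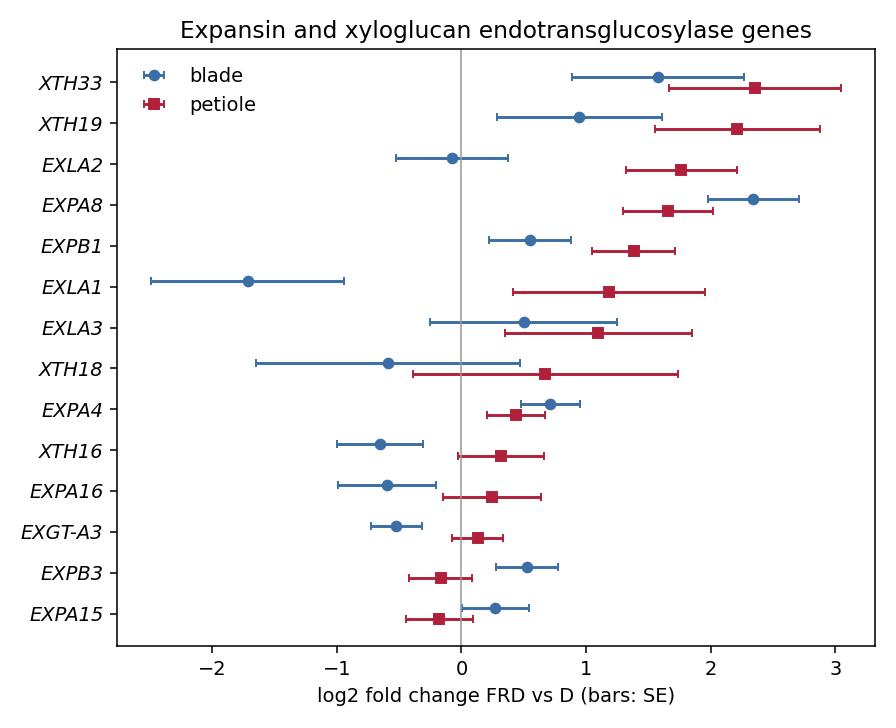
The 14 expansin and xyloglucan endotransglucosylase genes are listed on the vertical axis, with their log2 fold change after the pulse (FRD against D) on the horizontal axis in blades (blue circles) and petioles (red squares). Bars are standard errors of the fit with 3 arrays per group. EXPA8 is the member called over all genes in each tissue, at 2.34 in blades and 1.66 in petioles.

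Without single arrays 7 of the 16 genes named in petioles stayed called throughout: GH3.3, IAA29, IAA30, WES1, MGL, HAT2 and CYP71B22, and a floor at the 10th percentile of all ratios ended the calls of MYC4, AT5G57670, AT1G52770 and AT4G08340. With a variance trend GH3.3 (adjusted p = 0.753), AT1G52770 and AT4G08340 were not called, and with the 75th percentiles aligned FHL, MYC4 and AT1G52770 were not. The count of 249 fell to 33 with quantile normalization (5 of the 16 named genes), to 14 (3 of the 16) in a fit of the 6 compared arrays alone, and to 137, 123, 132 and 137 without petiole D replicate 1, petiole D replicate 2, petiole FRD replicate 1 and petiole FRD replicate 2.

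The pulse responses of both tissues overlapped. Of 127 probe sets raised in blades and 200 raised in petioles, 75 were shared, where independent lists would share 1.12. There were 3 shared falls against 0.0452 expected, and no probe set was called in opposite directions. The group means compared have no array in common, but the fit takes the spread of each probe set from all 18 arrays. Probe sets with a small spread are thus called more easily in both tissues. The numbers expected from independent lists, here and in the overlaps below, do not allow for that. Of the probe sets called in blades 93.2% had the same sign in petioles, and of those called in petioles 91.2% had the same sign in blades. The difference of the pulse response between tissues was itself called for 0 probe sets by limma, with 1197 at an unadjusted p under 0.05. That number is near the share of 0.05 of the 22746 tested that chance alone gives. The array-weighted limma fit called 3, a pseudocount at the 10th or 25th percentile 3 and 9, the floor at the 10th percentile 2 and the fit without any replicate 3 called 4, and leaving out 1 array gave 18 without blade D replicate 3, 6 without petiole D replicate 3 and 1 without petiole FRD replicate 2 or 3. Whether more genes responded in petioles than in blades is thus not shown gene by gene. As lists, the Aux/IAA genes (median difference 0.69, adjusted p = 0.0201) and the wall genes (0.81, adjusted p = 0.0406) were called as rising more in petioles, and both calls were lost with an estimated correlation (adjusted p = 0.068 and 0.427). Quantile normalization brought these medians to 0.43 and 0.49. The added list of all 28 wall genes with a symbol was not called for this difference.

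**Figure D4:**
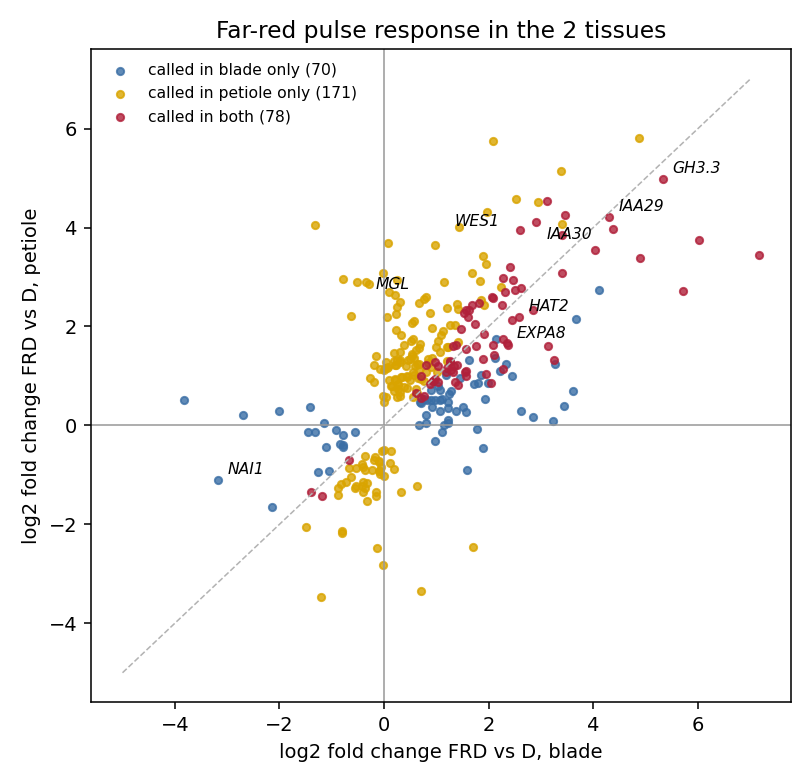
Each point is 1 of the 319 probe sets called for the pulse in at least 1 tissue, with its log2 fold change in blades on the horizontal and in petioles on the vertical axis. Colours mark the 78 called in both tissues (red), the 70 in blades alone (blue) and the 171 in petioles alone (yellow), and the dashed line marks equal change. The sign is positive in both tissues for 233 probe sets, negative in both for 54 and opposite for 32.

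In dark blades CML38, a calmodulin-like calcium sensor, rose by 4.1 ± 0.73 over white light (17.1-fold, adjusted p = 0.00293). MTPA1 rose by 3.66 ± 0.76, the receptor-like kinase gene B120 by 3.6 ± 0.47, and the pectin methylesterase gene ATPMEPCRB by 2.97 ± 0.33. WRKY53, a regulator of leaf senescence, rose by 2.53 ± 0.47, the gibberellin receptor gene GID1B by 2.39 ± 0.64, the glycosyltransferase gene UGT85A4 by 2.24 ± 0.25 and the zinc finger gene STZ by 2.19 ± 0.36. Further rises were those of AT5G05600 by 5.33 ± 0.54, AT3G23550 by 5.28 ± 0.78 and AT4G17470 by 4.86 ± 0.69.

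EXPA8 fell by 3.88 ± 0.36 log2 units in dark blades (adjusted p = 3.94e-05). The expansin gene EXPB1 (-2.44 ± 0.33) and the endoglucanase gene GH9C2 (-2.03 ± 0.24) were lower too. GI, which acts in the circadian clock and photoperiodic flowering, fell by 2.11 ± 0.37 (adjusted p = 0.00267). Falls were also called for the MADS-box gene AGL91 (-2.39 ± 0.54), the dioxygenase gene AOP1 (-2.16 ± 0.28), the cation exchanger gene CHX16 (-1.71 ± 0.51) and the subtilase gene SBT3.12 (-1.71 ± 0.47). Among locus codes, AT1G44070 (-3.94 ± 0.73), AT1G62690 (-3.65 ± 0.99) and AT2G27420 (-3.55 ± 0.8) fell most.

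All 4 dark-inducible or starvation genes measured in blades had positive changes, and 2 were called over all genes and adjusted over the list alone: AKINBETA1, a subunit of the energy-sensing SnRK1 kinase, at 1.98 ± 0.3 and MCCA, an enzyme of leucine breakdown, at 1.56 ± 0.28. The list was called with the preset correlation (adjusted p = 0.00784) and lost with an estimated correlation (adjusted p = 0.451). In an added list of 20 wounding, touch and calcium-responsive genes, 19 were positive and 5 were called over all genes, namely CML38, STZ, WRKY53, WRKY22 at 1.67 ± 0.25 and BIK1 at 0.84 ± 0.2, with 7 adjusted over the list alone (median 0.72, adjusted p = 0.000191, and adjusted p = 0.223 with an estimated correlation). That median was 0.39 with the 75th percentiles aligned. Of the 14 wall genes, 4 were lower (EXPA8, EXPB1, EXPB3 and EXPA15) and EXGT-A3 was higher over all genes, with 7 called adjusted over the list alone. The list was not called (adjusted p = 0.697), and its median of 0.40 and mean of -0.18 differ in sign. The control probe set for 25S ribosomal RNA was higher in the same blade D arrays, at 0.97 ± 0.2 against -0.08 ± 0.22 in WL (SD, n = 3). It stood at 0.34 ± 0.25 in blade FRD and 0.05 ± 0.26 in petiole D arrays, which were dark too. The blade D arrays are also the reference for the pulse in blades.

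Of the 22 genes named, AT1G62690, AT2G27420, CHX16, GID1B and SBT3.12 were lost on leaving out some single array of the groups compared, and GID1B rose by 1.37 without blade WL replicate 1. With ratios floored at their 10th percentile, EXPA8 shrank to -0.75 (adjusted p = 0.133) and its call was lost, as were those of AGL91, CHX16, SBT3.12, AT1G44070 and AT1G62690, while a variance trend ended those of AT5G05600, AT3G23550 and AT2G27420. The count of 2542, of which 60% were higher, changed to 160 with quantile normalization (11 of the 22 named genes), to 447 (17 of the 22) in a fit of the 6 compared arrays alone and to 1631 without blade WL replicate 1. Aligning the 75th percentiles gave 5024 calls with 13.5% higher, a setting that shifts the median of all genes by -0.33, since the white-light arrays have a narrower spread of ratios once each gene is divided by their median.

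Darkness gave a related picture in petioles. CYP71B22 rose by 2.99 ± 0.22 (7.92-fold, adjusted p = 2.79e-05), the subtilase gene SBT3.3 by 3.21 ± 0.87, CIL by 2.54 ± 0.47 and ATPMEPCRB by 2.1 ± 0.33. IQD22, which encodes a calmodulin-binding protein, rose by 1.94 ± 0.37, B120 by 1.9 ± 0.47, UGT85A4 by 1.8 ± 0.25 and UGT72E1 by 1.49 ± 0.41. AT3G23550 rose by 5.91 ± 0.78, AT1G26420 by 5.12 ± 1.24 and AT3G21080 by 4.3 ± 0.54.

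NGA1, a B3-domain transcription factor of lateral organ growth, fell by 3.18 ± 0.44 in dark petioles (adjusted p = 0.00128). The beta-glucosidase genes BGLU43 (-3.23 ± 0.86) and BGLU47 (-2.05 ± 0.46) fell, as did EXPB1 (-2.62 ± 0.33), TBL15 (-2.46 ± 0.54) and AOP1 (-2.21 ± 0.28). IAGLU, a glucosyltransferase that conjugates auxin, fell by 1.96 ± 0.38, and GI fell by 1.86 ± 0.37. The largest falls among locus codes were AT2G15020 (-4.93 ± 0.6), AT2G27420 (-3.94 ± 0.8) and AT5G57670 (-3.74 ± 0.73).

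AKINBETA1 at 1.22 ± 0.3 and MCCA at 1.12 ± 0.28 were again called in dark petioles, and 3 of the 4 starvation genes adjusted over the list alone, where ATL8 joined at 1.0 ± 0.28 (list adjusted p = 0.0032, and adjusted p = 0.343 with an estimated correlation). Of the 20 wounding, touch and calcium-responsive genes, 14 were positive and 5 were called over all genes, namely STZ, CML42, CML30, WRKY22 and BIK1, with 8 adjusted over the list alone (median 0.71, adjusted p = 0.00515, and adjusted p = 0.385 with an estimated correlation). Aligned 75th percentiles lowered that median to 0.43. Of the wall genes EXPA8 at -1.43 ± 0.36 and EXPB1 fell and EXGT-A3 rose by 0.89 ± 0.2, with 5 called adjusted over the list alone, and the list was not called (adjusted p = 0.654).

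Lost on leaving out some single array were AT1G26420, AT2G27420, B120, BGLU43, BGLU47, SBT3.3, TBL15 and UGT72E1, 8 of the 22 genes named, and a floor at the 10th percentile ended the calls of BGLU43, TBL15, BGLU47, IAGLU and AT5G57670. A variance trend ended those of B120, UGT72E1, GI, AT3G23550, AT1G26420, AT2G15020 and AT2G27420, and aligned 75th percentiles ended that of UGT72E1. The petiole count of 1274, with 61.6% higher, changed to 84 with quantile normalization (8 of the 22 named genes) and to 257 with the compared arrays alone (11 of the 22), rose to 2223 with array weights, and was 640, 605, 716 and 593 without petiole WL replicate 1, petiole WL replicate 2, petiole D replicate 2 and petiole D replicate 3. Alignment of the 75th percentiles gave 2907 with 13.3% higher, at a shift of all genes by -0.28, and the count without any replicate 3 was 705.

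Responses to darkness overlapped between tissues, with no array in common between the group means compared. They shared 564 rises against 52.6 expected from independent lists and 304 falls against 21.9, and 4 probe sets were called in opposite directions. The difference between tissues was called for 1 probe set, AT5G52050, which changed by 3.88 ± 0.36 in petioles and by -0.45 ± 0.36 in blades (difference 4.33 ± 0.51, adjusted p = 0.0198). The call was lost in 10 of 23 alternative settings, with adjusted p up to 0.284. The count was 2 with array weights, 5 with the 12 compared arrays alone, 7 without blade WL replicate 3, 2 without petiole WL replicate 1 or 2 or petiole D replicate 2, and 0 with quantile normalization, without any replicate 3, or without blade WL replicate 1 or 2, any blade D array, petiole WL replicate 3 or petiole D replicate 3. It was also 0 with the replicate number as a block, where AT5G52050 had a limma adjusted p = 0.0517. An unadjusted p under 0.05 was reached by 1506 probe sets, above the share of 0.05 of 22746 that chance alone gives. With 1 called, the larger number of calls in blades does not show which genes respond more strongly there.

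With pulse and darkness together, auxin genes were among those raised over white light in blades. GH3.3 rose by 8.26 ± 0.82 (adjusted p = 5.26e-05), IAA29 by 3.7 ± 0.38, IAA30 by 3.61 ± 0.38 and WES1 by 2.98 ± 0.23. CHI (AT2G43570) rose by 4.1 ± 1.06, MTPA1 by 3.5 ± 0.76, CML38 by 3.25 ± 0.73 and B120 by 3.05 ± 0.47. GI fell by 2.86 ± 0.37. Lower as well were the carboxypeptidase-like gene scpl22 (-3.43 ± 1.0), AOP1 (-2.15 ± 0.28), the glycosyltransferase gene GT72B1 (-2.01 ± 0.32), EXPB1 (-1.89 ± 0.33), TBL26 (-1.89 ± 0.41), AGL91 (-1.85 ± 0.54) and the AP2/ERF factor gene TINY2 (-1.83 ± 0.33). AT2G04050, AT3G23550 and AT4G09860 rose by 4.8 ± 0.69, 4.42 ± 0.78 and 4.35 ± 1.14, while AT5G34950 (-3.8 ± 1.08), AT3G61920 (-3.58 ± 1.0) and AT2G22180 (-3.55 ± 0.8) fell.

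The GH3 list rose in blades after pulse and darkness, with 2 of 5 called over all genes and adjusted over the list alone (adjusted p = 0.00108, 0.0159 with an estimated correlation). The Aux/IAA list was not called (adjusted p = 0.0564), with IAA29 and IAA30 called over all genes and adjusted over the list alone. An added list of 9 ATG8 autophagy genes was called as raised, with ATG8E at 1.15 ± 0.25 and ATG8F at 0.57 ± 0.13 called over all genes and 4 members adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.378 with an estimated correlation). Its median of 0.35 shrank to 0.04 when the 75th percentiles were aligned and to 0.21 with quantile normalization. The added list of 6 starch genes was called as lowered, with 2 members called over all genes and adjusted over the list alone, DPE1 (-0.93 ± 0.19) and PWD (-0.84 ± 0.17), the latter a kinase acting on starch (list adjusted p = 0.0419, and adjusted p = 0.239 with an estimated correlation). Of the wounding, touch and calcium-responsive genes 5 of 20 were called over all genes, all higher, and 9 adjusted over the list alone, of which 1 was lower (median 0.65, or 0.34 with the 75th percentiles aligned, adjusted p = 0.000284, and adjusted p = 0.21 with an estimated correlation).

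Of the 22 genes named, AGL91, AT2G22180, AT3G61920, AT4G09860, AT5G34950, CHI, CML38 and scpl22 did not stay called without every single array, and scpl22, AGL91, AT5G34950 and AT2G22180 were lost with the floor at the 10th percentile. A variance trend ended the calls of GH3.3 (adjusted p = 0.0801), AT3G23550 and AT3G61920, and the change of GH3.3 was 9.4 without blade WL replicate 3 and 5.98 with quantile normalization. That of AT3G61920 was -4.63 without blade FRD replicate 1 and -2.82 without blade FRD replicate 2. The blade count of 2537, with 57.5% higher, changed to 187 with quantile normalization (8 of the 22 named genes), to 631 with the compared arrays alone (13 of the 22) and to 1690 without blade WL replicate 1. Aligned 75th percentiles gave 4643 with 14.7% higher, at a shift of -0.31.

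Among genes with a symbol, the largest rises over white light in petioles were those of GH3.3 at 5.75 ± 0.82 (adjusted p = 0.000881), IAA29 at 5.15 ± 0.38 and WES1 at 4.19 ± 0.23. IAA20 rose by 3.61 ± 0.78, EXO, a growth gene induced by brassinosteroids, by 3.9 ± 0.86, the MADS-box gene AGL42 by 3.73 ± 0.98, the transcription factor gene UPB1 by 3.6 ± 0.86 and MGL by 3.48 ± 0.23. AGO7, an ARGONAUTE of small RNA pathways, fell by 3.47 ± 0.6 (adjusted p = 0.00293). Falls were also called for the small heat shock protein gene ATHSP22.0 (-3.1 ± 0.77), BGLU47 (-2.69 ± 0.46), LpxA (-2.62 ± 0.73), CYP71B26 (-2.57 ± 0.37), CHR42 (-2.44 ± 0.66), the flavonol glycosyltransferase gene UGT78D1 (-2.1 ± 0.32) and GI (-2.09 ± 0.37). AT5G02580, AT5G62280 and AT3G46390 rose by 5.59 ± 1.02, 5.38 ± 0.79 and 4.43 ± 1.08, while AT1G52770 (-5.11 ± 0.77), AT2G15020 (-4.73 ± 0.68) and AT4G16880 (-4.28 ± 0.55) fell.

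Both auxin lists rose in petioles over white light. Aux/IAA genes had 3 of 7 members called over all genes and 4 adjusted over the list alone (adjusted p = 0.00382, 0.0197 with an estimated correlation), and GH3 genes 2 of 5 and 5 of 5, GH3.9 among them lower at -0.85 ± 0.3 (adjusted p = 0.00265, 0.0197 with an estimated correlation). The wall list was called as raised at a median of 1.06, lost with an estimated correlation (adjusted p = 0.0327 against adjusted p = 0.259): over all genes XTH19 rose by 2.49 ± 0.66 and EXGT-A3 by 1.02 ± 0.2 while EXPB1 (-1.23 ± 0.33) and EXPA15 (-0.99 ± 0.27) fell, and 10 were called adjusted over the list alone, 7 of them higher. The 4 starvation genes were called as raised (adjusted p = 0.0067, and adjusted p = 0.203 with an estimated correlation), with 2 members called over all genes and adjusted over the list alone. Of 20 wounding, touch and calcium-responsive genes 4 were called over all genes and 8 adjusted over the list alone, all higher (median 0.75, or 0.43 with the 75th percentiles aligned, adjusted p = 0.000305, and adjusted p = 0.14 with an estimated correlation). The starch list was called as lowered, with all 6 members negative, APL4, a subunit of the enzyme that makes ADP-glucose, called over all genes (-1.17 ± 0.3) and 3 adjusted over the list alone (adjusted p = 0.00783, and adjusted p = 0.14 with an estimated correlation).

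Leaving out some single array ended the calls of AGL42, AT3G46390, ATHSP22.0, CHR42, IAA20, LpxA and UPB1, 7 of the 22 genes named, and the floor at the 10th percentile those of ATHSP22.0, BGLU47, LpxA, CHR42 and AT1G52770. A variance trend ended those of GH3.3 (adjusted p = 0.272) and AT2G15020. The change of AGO7 was -4.46 without petiole FRD replicate 3. The petiole count of 1891, with 53.4% higher, changed to 183 with quantile normalization (14 of the 22 named genes) and to 590 with the compared arrays alone (15 of the 22), and was 1152, 1170 and 1257 without petiole WL replicate 1, petiole WL replicate 2 and petiole FRD replicate 2. Aligned 75th percentiles gave 4385 with 12.7% higher, at a shift of -0.31.

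Against white light, pulse and darkness raised 649 probe sets in both tissues, where independent lists would share 64.7, and lowered 481 in both against 41.8, with 1 called in opposite directions. The difference between tissues was called for 8 probe sets, and 1681 had an unadjusted p under 0.05, also above the chance share of 0.05 of 22746. MGL rose by 3.48 ± 0.23 in petioles and stood at 0.89 ± 0.23 in blades (difference 2.59 ± 0.33, adjusted p = 0.0222). AT5G52050 and AT3G55840 changed more in petioles, by 3.69 ± 0.51 and 3.0 ± 0.43, and AT3G05980, AT5G03230 and AT2G23840 had differences of -3.56 ± 0.54, -1.83 ± 0.27 and -1.43 ± 0.21. The other 2 probe sets are unnamed. None of the 6 named genes stayed called when each array was left out in turn, and AT3G05980 and AT2G23840 were lost with the floor at the 10th percentile or a variance trend. The count was 17 without petiole FRD replicate 3, 8 without blade WL replicate 3, and 1 to 5 without any other of the 12 arrays. The count was 38 with a pseudocount at the 10th percentile (20 higher, 18 lower, against 3 and 5 without it), 40 with 1 at the 25th, 18 with the floor at the 10th, 34 with array weights, 13 without any replicate 3, and 0 with quantile normalization or with the 12 compared arrays alone.

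Light-harvesting genes, fixed beforehand as mesophyll markers, were not called in any of the 6 light comparisons. Their 3 measured members, LHCB4.1, LHCB4.2 and LHCB4.3, had medians from -0.29 to -0.04, with list adjusted p from 0.143 to 0.792. The 3 gibberellin receptor genes were not called as a list either (adjusted p from 0.173 to 0.937), though GID1B rose in dark blades and GID1A, at 0.89 ± 0.2, in blades after pulse and darkness. Markers of xylem, phloem, epidermis and leaf base had too few named probe sets to be tested.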

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

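Apart from the division of the redrawn tissue labels, no test in this part was chosen after its result was seen. The outcomes on array scaling, on single arrays for the darkness count and on redrawn tissue labels were read differently once their values were known.

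Between tissues, the change from white light to D differed for AT5G52050 by 4.33 ± 0.51 log2 units (petiole 3.88, blade -0.45, adjusted p = 0.0198). From white light to FRD the difference, petiole minus blade, was 3.69 for AT5G52050 (3.73 and 0.05), 3.0 for AT3G55840 (3.41 and 0.41) and 2.59 for MGL (3.48 and 0.89). It was -3.99 for probe set 250620_at (-0.55 and 3.44), -1.95 for probe set 252291_s_at (0.34 and 2.29), -3.56 for AT3G05980 (-2.55 and 1.01), -1.83 for AT5G03230 (-0.20 and 1.63) and -1.43 for AT2G23840 (-2.17 and -0.74). Adjusted p for these 8 ran from 0.00727 to 0.0439. As lists, Aux/IAA genes differed in their response to the pulse (median difference 0.689, adjusted p = 0.0201), and so did wall genes (0.806, adjusted p = 0.0406). Wall genes also differed between FRD and white light (0.64, adjusted p = 0.00833), a comparison that uses the same FRD arrays. None of these 3 list calls held with an estimated correlation (adjusted p = 0.068, 0.427 and 0.379). The added list of all 28 wall genes with a symbol was called for neither difference.

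When tissue labels were redrawn within each light treatment, 8 of 100 draws, the real one included, gave at least the real 1 probe set for D against white light (highest other 58), and 8 of 100 gave at least the real 8 for FRD against white light (highest other 131). These draws leave chance open. White-light ratios are centred by tissue, so a draw that keeps or swaps all labels of the other treatment holds the real difference between tissues. It also holds the error of the white-light medians, which cancels under the real labels alone. All 7 other draws as large, in each comparison, are of that kind. Of the remaining 90 and 92 draws 0 reached the real count (highest 0 and 1), a division made after the values were seen. Each of those mixes blade and petiole arrays within groups of the other treatment, which can widen the spread within groups and so lower the count. Neither kind of draw is thus a fair measure of what chance gives. The draws say nothing on FRD against D, where a real count of 0 is matched by 100 of 100 whatever the data. Its highest other draw called 3304 probe sets and swaps the tissue labels of all D arrays, so the white-light medians do not cancel in it. For the 6 light comparisons within a tissue, the 10 possible splits of 6 arrays are too few for a share under 0.05. In each of them only the real split, 1 of 10, gave as many calls: 148 against a highest other of 4, 249 against 1, 2542 against 2, 1274 against 3, 2537 against 3 and 1891 against 2. Every other split mixes both light treatments within its groups, which can widen the spread and lower the count. These lower counts are thus no fair measure of what chance gives either.

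Control probe sets outside the comparisons moved between dark and white-light blades. The probe set for 25S ribosomal RNA was higher in D by 1.05 ± 0.20 (adjusted p = 0.00807), and 1 for the Bacillus control gene phe by 1.72 ± 0.35 (adjusted p = 0.00807). Whether Bacillus transcripts were added to these samples is not known here. The 27 Bacillus controls had a median SD within groups of 1.22, against 0.223 for 18 hybridization controls.

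More probe sets rose than fell after the far-red pulse, 85.8% of the calls in blades and 80.3% in petioles. Noisy probe sets as the source are argued against, since among calls with a residual SD under the median 84.7% of 98 in blades and 75.5% of 159 in petioles were higher. Aligned 75th percentiles left 88.9% and 79.9% higher. That alignment moves the median of all probe sets by only 0.0254 and -0.0324, so it could not have turned the shares. Array scaling, as a shift common to all probe sets, is argued against by other values, read after this outcome was seen. The median change of all probe sets was -0.0223 in blades and -0.0182 in petioles, while called changes had median sizes of 1.57 and 1.35. Scaling that acts on some probe sets alone, or that was hidden by the unknown scaling before the ratios were deposited, stays open.

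Darkness gave 2.0 times as many calls in blades as in petioles. A larger spread between petiole arrays was not found, since their median SD was 0.884 times that of blades. The fit pools the spread over the 6 groups, so a spread particular to 1 tissue does not enter its errors alone. Whether the difference in spread affects the counts was not tested. The lowest ratio of counts with 1 array left out was 1.28, under the 1.5 set beforehand as the mark of 1 aberrant array. Since 3 of 12 arrays, all from blades, gave a ratio under that mark, and each removal also leaves blades with fewer arrays, the outcome was read as open once seen. Larger effects in blades cannot be told apart from equal ones, as the ratio of noise-corrected SDs was 1.06, and 0.996, 1.03 and 1.11 without replicate numbers 1, 2 and 3.

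Wounding, touch and calcium-responsive genes were called as higher in D than in white light with the preset correlation, with 5 of 20 members called in each tissue. Neither list call held with an estimated correlation (adjusted p = 0.223 in blades and adjusted p = 0.385 in petioles). RNA degradation, which needs a rise of the 3' minus 5' difference of actin and GAPDH controls, is argued against by a change of -0.133 on average (blades 0.0646 to -0.145, petioles 0.0676 to 0.0114), though actin alone went from 0.102 to 0.197 in petioles with overlapping arrays, and 25S ribosomal RNA rose in the dark blades. A single aberrant array is argued against as well, since the lowest list median with 1 array left out was 0.610. Handling before or at harvest cannot be told apart from darkness, because each treatment was handled as its own group, and the median of 0.723 in blades could come from either.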

How the results depend on the processing

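Of the tests below, the fit without replicate 3 was chosen after the data had been seen, and the pseudocount at the 10th percentile and the variance trend, named beforehand for the fit itself, were made alternatives once the unit was known. With 3 arrays per group and ratios in place of levels, signal over background is unknown and dim probe sets could not be left out, which limits every count. Comparisons are given in the order blade, petiole and their difference. No named gene changed sign in any setting, but aligned 75th percentiles turned the majority of calls from higher to lower in 4 comparisons. The floor at the 1st percentile and the variance trend kept every count within 1.5 times. Of 127 results for named genes, 74 were no longer called with quantile normalization, 67 with the compared arrays alone, 43 without replicate 3, 30 with the floor at the 10th percentile, 23 with either pseudocount, 21 with the variance trend, 7 with the floor at the 1st percentile, 5 with the block, 4 with aligned 75th percentiles and 2 with array weights. GH3.3 was among those lost with the variance trend, in all 4 comparisons that name it. That trend runs on the mean log2 ratio, which follows the size of a gene's response and not its level. It is thus no fair check for genes with large changes. Leaving out 1 array moved the fold of 26 of the 127 by over 1.5 times. EXPA8 had no difference left between FRD and D in blades with the floor at the 10th percentile, because the arrays of both groups then lay below it.

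Quantile normalization gave 32 and 33 calls for FRD against D, 160, 84 and 0 for D against WL, and 187, 183 and 0 for FRD against WL. This setting gives all arrays the same distribution of ratios, so it widens the white-light arrays, which division by their median had narrowed. The fit pools the spread over the 6 groups, so this reaches FRD against D too. How much of the loss of calls comes from it was not tested. The 0 differences by limma compare with 1 and 8 without quantile normalization, and 1506 and 1681 probe sets had an unadjusted p under 0.05 there. The compared arrays alone gave 10 and 14 for FRD against D, 447, 257 and 5 for D against WL, and 631, 590 and 0 for FRD against WL, with fewer residual degrees of freedom. Aligned 75th percentiles gave 5024 and 2907 for D against WL (679 and 388 higher) and 4643 and 4385 for FRD against WL (682 and 559 higher). Division by the white-light median narrows the white-light arrays, so this alignment moves the other arrays by construction. For FRD against WL in petioles it also moved the list medians of Aux/IAA genes from 0.43 to 0.12, starvation genes from 0.92 to 0.61, starch genes from -0.47 to -0.79 and glutathione transferases from -0.53 to -0.84, and in blades that of starch genes from -0.47 to -0.78.

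Array weights gave 2223 for D against WL in petioles and 3, 2 and 34 for the tissue differences in FRD against D, D against WL and FRD against WL. For the tissue differences in FRD against D and FRD against WL, the floor at the 10th percentile gave 2 and 18, the pseudocount at the 25th percentile 9 and 40, and the pseudocount at the 10th percentile 3 and 38. Without replicate 3 in every group, D against WL in petioles gave 705, and the tissue differences in FRD against D, D against WL and FRD against WL gave 4, 0 and 13. The cause was not tested for these.

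Replicate numbers were not taken to pair the arrays, since only 7 of 45 same-number pairs had a correlation of deviations above 0.1. All 7 are of number 3, and 30 of 45 pairs correlated best with their own number where chance gives 15, a hint from the data that arrays of number 3 share a deviation. For number 3 alone, 14 of 15 pairs did so. The replicate block gave more calls in every comparison within a tissue. It gave 181 and 289 for FRD against D, 3359 and 2039 for D against WL, and 3386 and 2605 for FRD against WL. The tissue differences in FRD against D, D against WL and FRD against WL had 1, 0 and 16 calls with the block. Of 225 gene list tests 29 were called, against 44 with the replicate block, all 29 among them (not called without it were, for example, Aux/IAA genes in blades, adjusted p = 0.0329, and plastid photosynthesis genes in petioles, adjusted p = 0.0388, for FRD against WL), and 11 with an estimated correlation. By fry 25 of the 29 were called.

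Leaving out 1 array gave 1631 (without blade WL replicate 1) to 2148 for D against WL in blades and 593 (without petiole D replicate 3) to 955 in petioles. For FRD against WL it gave 1690 (without blade WL replicate 1) to 2107 in blades and 1152 (without petiole WL replicate 1) to 1457 in petioles. For FRD against D it gave 92 (without blade FRD replicate 2) to 205 (without blade D replicate 3) in blades and 123 (without petiole D replicate 2) to 249 in petioles. The tissue differences ran from 0 to 18 (without blade D replicate 3) for FRD against D, 0 to 7 (without blade WL replicate 3) for D against WL, and 1 (without blade FRD replicate 1) to 17 (without petiole FRD replicate 3) for FRD against WL. A fit with fewer arrays has less power, which lowers counts by construction.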

Other observations

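No test in this part was chosen after its result was seen.

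Among 47 glycosyltransferase genes of the UGT family, an added list, darkness changed 7 in each tissue. Over all 22746 probe sets it changed 2542 in blades and 1274 in petioles, so 7 is close to the overall share in blades and above it in petioles. Whether the family differs from other genes in how often it was called was not tested. UGT85A4, UGT85A2, UGT71C5 and UGT72E1 rose in both, the last by 1.42 ± 0.41 in blades and 1.49 ± 0.41 in petioles. UGT76E11 fell by 1.48 ± 0.27 in blades and fell by 1.47 ± 0.27 in petioles, and UGT78D1 fell by 1.47 ± 0.32 and fell by 1.19 ± 0.32. The list moved both ways and was not called (adjusted p = 0.85 in blades and 0.648 in petioles). With pulse and darkness 9 were called in petioles, 7 of them lower, among them UGT78D2 (-1.45 ± 0.25) and UGT85A5 (-1.99 ± 0.4). In blades 6 were called, 3 higher and 3 lower. Over all probe sets these counts were 1891 in petioles and 2537 in blades, so 6 is close to the overall share in blades and 9 above it in petioles. Over all members in petioles 24 were higher and 23 lower, and the list was called in neither tissue (adjusted p = 0.587 in petioles and 0.985 in blades). Adjusted over the list alone, 7 and 12 were called for darkness in blades and petioles and 8 and 13 for pulse and darkness.

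Of 24 nuclear genes of photosynthesis, an added list, 22 were lower in petioles after pulse and darkness than in white light (median -0.20, or -0.52 with the 75th percentiles aligned, adjusted p = 0.00783, and adjusted p = 0.504 with an estimated correlation), and none was called over all genes or adjusted over the list alone. The 43 plastid genes of photosynthesis had a median of 0.15 there and were not called (adjusted p = 0.203). The 14 glutathione transferase genes were called as lower in the same comparison, with GSTU27 at -1.29 ± 0.21 the single member called over all genes or adjusted over the list alone (list adjusted p = 0.0382, and adjusted p = 0.14 with an estimated correlation).

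A hypothesis was that darkness moves genes raised by the pulse the opposite way, tested across tissues so that the changes compared share no array. Of 127 probe sets raised by the pulse in blades, 68 (53.5%) were lower in dark petioles, against 50.4% of all probe sets, a share short of the 60% set beforehand, and their median of -0.03 lay at percentile 25.5 of 10000 random sets. In dark petioles 11 of them were called lower and 3 higher. Of 200 raised in petioles, 126 (63.0%) were lower in dark blades, against 51.7% of all probe sets, with a median of -0.20 at percentile 0.01, and 26 were called lower and 14 higher there. The test was met for genes raised in petioles and not for those raised in blades, and the difference between both was not tested. Random sets take genes as independent, so the percentiles do not allow for genes that move together. A deviation common to the D plants of both tissues would enter the compared changes with opposite sign. Deviations of blade D and petiole D arrays with the same number correlated at 0.0722, 0.00633 and 0.112, so separate arrays may not be fully independent.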
